A study of Homo sapiens with 6 samples.

How the data were processed

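Rheumatoid arthritis synovial fibroblasts, the connective tissue cells of the joint lining, were profiled on 6 one-colour Affymetrix oligonucleotide arrays. Per the labels, the cells received an adenovirus carrying a dominant negative IκB, an inhibitor protein that holds the transcription factor NF-κB in the cytoplasm, or the control adenovirus Adtet. Tumour necrosis factor α (TNF-α) was added 18 h later. RNA was taken 3 h after TNF-α, which the labels state for 5 of the 6 arrays and leave out for IκB array 1. The 6 arrays form 2 groups of 3, taken from the sample titles. The title of IκB array 1 carries no replicate number, so its 1 is only a name and does not pair it with Adtet array 1. The labels do not say whether arrays of a group came from separate cultures or donors, so the p-values measure only the spread between these arrays, which may be technical. No arrays without virus or without TNF-α were analysed here, so neither the response to TNF-α nor that to the virus was measured.

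The deposited table holds 1 linear intensity per probe set and array for 12625 probe sets, of which 67 are controls. The software behind these intensities is not given in the sources used here. The values carry a common scale, since the mean after trimming 2% at each end was 150 on every array, and between 22.4% and 26.5% of the values of an array were at or below 0. Gene symbols came from the platform annotation supplied with the table, updated through gene IDs with RefSeq gene names of assembly GRCh38.p14. Of all probe sets, 10943 had 1 symbol, 545 had several and 1119 were not listed. Gene IDs of 10934 matched RefSeq. Genes were named only from probe sets with 1 symbol.

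Intensities were used as deposited, because the trimmed means differed by less than 10% between arrays. The floor planned before the data were examined was the 20th percentile of all values, which turned out to be -6.5 and has no logarithm. The 40th percentile, an intensity of 27 that had been listed as another floor to try, took its place. Values under 27 were raised to 27, and log2 was taken. Probe sets with a mean log2 value above the 40th percentile of all probe sets, 5.15, were tested, which left 7530 after removal of controls. A fold change in which all 3 arrays of a group lay at or below the floor is a lower bound, given as "at least", and list medians hold such genes at their bound. Folds are differences of mean log2 values and can differ from the ratio of the mean intensities printed beside them. Where only 1 or 2 arrays of the dimmer group lay at or below the floor, the fold is a lower bound on that log2 scale only, because the floor raises those values, and the number of such arrays is given. The floor also removes the spread within such a group, so its p-value leans on the other group and on the moderated variance.

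The comparison was fitted with limma 3.58.1 (R 4.3.3, lmFit, then eBayes with a mean-variance trend) as IκB dominant negative minus Adtet. The test was two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Every adjusted p of a gene is from that limma fit unless another is named. Standard errors (SE) are the moderated ones of the fit, and levels are mean intensity ± SD over 3 arrays. Where a gene had several probe sets, the one with the highest mean represented it. Before the data were examined, 18 gene lists were fixed, among them markers of macrophages, lymphocytes and endothelial cells. Each was tested with camera, a limma test of whether the genes of a list shift against all others. Camera used a preset inter-gene correlation of 0.01, with adjustment over the 18 lists. Camera with an estimated correlation and fry stood beside it. Fry asks whether the genes of a list move one way on balance, without reference to other genes.

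Genes were named by a rule set before the data were examined. It took the IκB genes, the 12 largest changes per direction among genes past the threshold whose groups did not overlap, and up to 4 genes per list by smallest unadjusted p. Bounded changes entered at their bound and have no order among themselves. Other members of a list, and further probe sets of a named gene, are named where a count of members is spelled out or probe sets differ, and were chosen after their values were seen. XIST and Y-linked genes were left out of every table of named genes.

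The fit was tested on simulated data. Each probe set took its mean in the real table plus normally distributed noise, with a spread drawn from probe sets of similar mean. Known changes were added to some probe sets. The simulated arrays did not differ in quality, so the rates hold for such noise only. In that simulation of the same comparison over 7530 probe sets, limma recovered 36.7% of changes of 1 on the log2 scale, 62% of changes of 2, 80% of changes of 3 and 92% of changes of 4. Of its 140 calls 5 were false, and none of 10 unchanged lists was called by camera. The noise was drawn separately for each probe set, so the genes of a list were not correlated. The list result therefore cannot show how often camera calls correlated lists by mistake. A first simulation of that comparison over 7530 probe sets, with changes of 0.5, 1 and 2, recovered 1.52%, 18.5% and 44.6% and missed the bar of 60% that had been set for changes of 2. After that result the sizes were replaced by 1 to 4 and the bar moved to changes of 4. In both simulations most changes of 1 or less were missed, and recovery of changes of 2 differed between them. The number of arrays, 3 per group, limits the precision.

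Alternatives covered the scaling between arrays, the floor, the filter, the variance model, array weights, the gene level, the threshold, each array left out in turn, and a block on the replicate numbers that the titles of both groups share. The numbers were compared as a possible pairing. RNA quality was read from the 3′ over 5′ intensity ratios of the actin and GAPDH control probe sets, with an exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.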

Results

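Transcript levels were measured on 6 arrays of TNF-α-treated synovial fibroblasts, 3 with the IκB dominant negative and 3 with Adtet. Between 59.3% and 60.9% of the probe sets of an array lay above the floor. Correlations of log2 values across probe sets, which are not independent replicates, within the Adtet group were between 0.902 and 0.929. IκB arrays 2 and 3 correlated at 0.923, and IκB array 1 correlated with them at 0.873 and 0.849. Against the Adtet arrays, IκB arrays 2 and 3 correlated at 0.846 to 0.875, a range that includes their correlations with IκB array 1, and IκB array 1 at 0.772 to 0.805. The 18S ribosomal RNA control probe sets of IκB array 1 read 5, -60.8 and -247, whereas those of the other 5 arrays ranged from 376 to 2298. The actin 3′ over 5′ ratio was 1.13 ± 0.103 (SD, n = 3) with the IκB dominant negative and 1.22 ± 0.0347 with Adtet (exact permutation test, two-sided, p = 0.3). The GAPDH ratio was 0.785 ± 0.0448 (n = 3) and 0.673 ± 0.0327, with exact p = 0.1, the smallest that 3 against 3 arrays allow.

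The comparison asked which genes of TNF-α-treated fibroblasts differ when NF-κB is held by a dominant negative IκB. With it, transcripts for the adhesion receptors VCAM1 and ICAM1, the cytokine IL6, the chemokines CCL2, CXCL2 and CXCL8, and a list of interferon-stimulated genes were lower than with Adtet. VCAM1 was at least 71.9-fold lower and CXCL8 25.4-fold. IL6 fell from 1289 ± 154 (SD, n = 3) to 11.0 ± 18.5, with 2 of the 3 IκB dominant negative arrays at or below the floor, a change of at least 45.7-fold (log2 fold change -5.52, SE 0.188, adjusted p = 1.06e-05). The transcript of DUSP4, a phosphatase that inactivates MAP kinases, rose at least 20.3-fold. HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, rose 4.51-fold.

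In total 392 of 7530 probe sets passed the threshold (1656 at an unadjusted p under 0.05), 177 higher and 215 lower with the IκB dominant negative. Of the 392, 31 had no symbol or several. Among 5467 tested genes, each represented by its brightest probe set, 139 were higher and 160 lower. Changes of at least 8-fold were 35 among the lower and 2 among the higher probe sets. The 2 groups did not overlap for any of the 392, and they did not overlap for 30.0% of all tested probe sets, where chance gives 10%. The median log2 fold change of all tested probe sets was 0.020. Without IκB array 1, which stood apart, 312 probe sets passed, 117 higher and 195 lower. The count was 180 without IκB array 2, and 168, 163 and 188 without Adtet array 1, 2 and 3, each fit having fewer arrays. The higher probe sets among these were 57, 74, 64 and 65.

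NFKBIA encodes IκBα, and whether its probe set detects the transgene is unknown. Its intensity was 112, 123 and 297 on the IκB dominant negative arrays and 1716, 1788 and 1832 on the Adtet arrays (log2 fold change -3.48, SE 0.345, adjusted p = 0.0016). NFKBIE, which encodes IκBε, fell 4.06-fold, from 216 ± 8.01 to 53.2 ± 5.70 (n = 3; adjusted p = 0.00387). The NFKBIB probe set was at or below the floor on all 6 arrays and was not tested.

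NF-κB family and feedback genes fell as a list, with 9 of 18 members lower, none higher and a median log2 fold change of -1.76 (camera adjusted p = 1.41e-10, and 0.0489 with an estimated correlation). With the floor at the 60th percentile, a setting chosen after seeing the data, the median was -0.81 and the list still passed. TNFAIP3, the ubiquitin-editing inhibitor A20, fell 23.4-fold from 1931 ± 138 to 83.2 ± 15.8 (n = 3). TNFAIP2 fell 13.1-fold. The NF-κB subunit genes NFKB2 and NFKB1 fell, NFKB1 by 3.08-fold and NFKB2 at least 7.74-fold by its brightest probe set, with 2 of the 3 lower arrays at or below the floor. The 5 tested probe sets of NFKB2, each with dim arrays held at the floor, had log2 fold changes from -2.95 to -0.97, and 3 of them passed. TNIP1, BIRC2 and TRAF1, of which 1 of 2 probe sets passed, completed the 9 with NFKBIA and NFKBIE. Adjusted over the list alone, 12 members were lower.

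Of 14 tested chemokine genes 9 fell and 1 rose, with a median log2 fold change of -3.86 (camera adjusted p = 8.34e-11, and 0.0178 with an estimated correlation). The monocyte attractant CCL2 fell 30.9-fold, from 2649 ± 315 (SD, n = 3) to 86.2 ± 16.2, by its brightest probe set. All 3 tested probe sets of CCL2 passed, with log2 fold changes from -4.95 to -2.96. The neutrophil attractants CXCL8 and CXCL6 fell 25.4-fold and 21.9-fold, and CXCL2 at least 29.8-fold, with 2 of the 3 lower arrays at or below the floor. CXCL1, CXCL3, CXCL5, CCL5 and CCL20 also fell. CXCL12, a chemokine that stromal cells make constitutively, rose 2.31-fold from 162 ± 11.3 to 376 ± 59.5 (adjusted p = 0.00929). The counts over the list alone were again 9 lower and 1 higher. Without the filter on dim probe sets, the median over the chemokines on the array moved to -0.93, with the list still past the threshold.

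Cytokine and growth factor genes fell as a list (camera adjusted p = 5.19e-06, and 0.0249 with an estimated correlation). Of 15 members 6 were lower and 1 was higher, with a median log2 fold change of -0.67. Besides IL6, the list held IL1B, which fell 5.64-fold from 1034 ± 74.3 to 187 ± 49.5 (n = 3), and IL32, which fell at least 16.8-fold from 675 ± 58.0, with 2 of the 3 lower arrays at or below the floor. IL1RN, the interleukin-1 receptor antagonist, fell from 258 ± 17.2 to 45.7 ± 32.8, at least 6.14-fold by mean log2 values with 1 such array, and IL15 and FGF2 were lower too. VEGFA, the endothelial growth factor, rose 1.85-fold. The fold of IL1B is that of its brighter probe set, and both of its 2 probe sets passed, with log2 fold changes of -4.17 and -2.50. Adjusted over the list alone, 8 were lower and 1 higher. Without the filter on dim probe sets the median was -0.17 with 4 lower, and the list still passed. Without Adtet array 1, 2 or 3 the count of lower members was 3 in each case and that of higher members 0 (9, 10 and 8 members at an unadjusted p under 0.05 in limma), and without IκB array 2 that of higher members was 0 (9 at that p). The IL32 call was lost with the generalised log2 without a floor (adjusted p = 0.0557), a setting chosen after seeing the data. The IL1RN call was lost without IκB array 1 or any 1 of the Adtet arrays, with adjusted p between 0.0606 and 0.0881.

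Among 16 adhesion molecules only ICAM1 and VCAM1, receptors for leukocyte integrins, passed the threshold, also when adjusted over the list alone. ICAM1 read 1873 ± 104 (SD, n = 3) with Adtet and lay at or below the floor on all IκB dominant negative arrays, at least 69.3-fold lower (adjusted p = 2.85e-06). VCAM1 was at least 71.9-fold lower, and both of its probe sets passed. The list as a whole did not pass (camera adjusted p = 0.138), and its median (0.01) and mean (-0.75) differed in sign, the median lying below 0 without any 1 array other than IκB array 2 (-0.13 to -0.029) and under the 75th percentile scaling (-0.010). By fry, which asks only for movement on balance, it was lower (adjusted p = 0.0004). Without IκB array 1 the adhesion list passed camera at an adjusted p of 0.0497, within a range of 0.0497 to 0.294 over its alternatives.

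**Figure D1:**
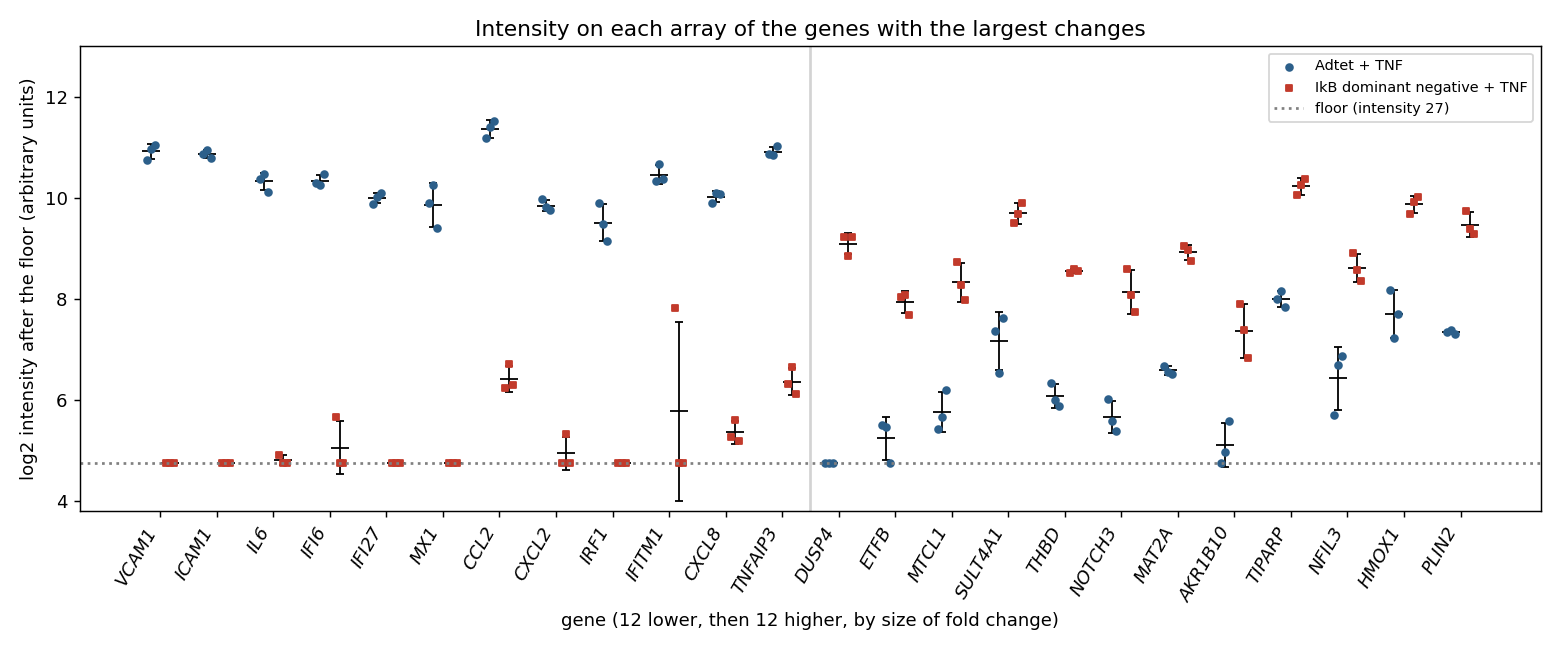
Log2 intensity after the floor (y axis, arbitrary units) on each array for the 12 genes with the largest falls and the 12 with the largest rises (x axis), bounded ones at their bound, where circles are Adtet arrays, squares are IκB dominant negative arrays, horizontal marks and bars are the mean ± SD of 3 arrays, and the dotted line is the floor at an intensity of 27. All squares of ICAM1 and VCAM1 lie on the floor, and the circles of DUSP4 do.

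Interferon-stimulated genes fell, with 20 of 39 lower, none higher and a median log2 fold change of -1.12 (camera adjusted p = 4.08e-22, and 0.0178 with an estimated correlation). IFI6 fell from 1301 ± 100 (SD, n = 3) to 18.2 ± 28.5, at least 39.0-fold, with 2 of the 3 lower arrays at or below the floor. IFI27, MX1, which encodes an antiviral GTPase, and the transcription factor gene IRF1 were at least 37.8-fold, 34.4-fold and 27.1-fold lower. ISG15, which encodes a ubiquitin-like modifier, fell 5.66-fold from 2406 ± 182 to 425 ± 34.9. The antiviral genes OAS1, OAS2, IFIT1 and IFIT3 and the immunoproteasome genes PSMB8 and PSMB9 were among the others. Adjusted over the list alone, 27 were lower. IFITM1 fell at least 25.6-fold with a wide spread on the IκB dominant negative arrays (49.3 ± 163), of which 2 lay at or below the floor. The IFITM1 call was lost without any 1 array other than IκB array 1, with adjusted p between 0.0523 and 0.079.

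Of 13 anti-apoptotic genes 5 fell and none rose, with a median log2 fold change of -0.70 (camera adjusted p = 9.21e-07, and 0.0249 with an estimated correlation). TNFAIP8 fell 9.92-fold, from 906 ± 31.1 (SD, n = 3) to 93.4 ± 23.3, and IER3 fell 3.41-fold. TNFAIP3, TRAF1 and BIRC2, which the NF-κB list also holds, were the others, and 8 were lower over the list alone. Of 20 pro-apoptotic genes 2 were lower, both by the full adjustment and over the list alone. These were DAXX at 1.99-fold by 1 of its 2 probe sets and BID at least 5.27-fold, with 2 of its 3 lower arrays at or below the floor. That list did not pass (camera adjusted p = 0.342), and its median (0.07) and mean (-0.25) differed in sign, the median ranging from -0.060 to 0.096 with single arrays left out and lying below 0 without IκB array 1 or 2. Without IκB array 2 or any 1 of the Adtet arrays, 3 anti-apoptotic members passed, and the TRAF1 call was lost (adjusted p 0.0716 to 0.0881). The BID call was lost without any 1 array other than IκB array 3 (adjusted p 0.0767 to 0.112), which left 1 pro-apoptotic member.

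Cell cycle and DNA replication genes fell as a list, with 12 of 38 lower, none higher and a median log2 fold change of -0.89 (camera adjusted p = 3.74e-12, and 0.0249 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell at least 4.65-fold from 158 ± 22.5 (SD, n = 3) to 20.8 ± 27.9, with 2 of the 3 lower arrays at or below the floor. The spindle gene TPX2 fell 2.65-fold, the spindle checkpoint kinase gene BUB1B 3.19-fold, and TOP2A, the topoisomerase of dividing cells, 1.99-fold. AURKB, CDK1, CCNB1, CCNB2, KIF11, UBE2C, RFC4 and PTTG1 were also lower, and 22 members were lower over the list alone. With the floor at the 60th percentile, chosen after seeing the data, the median was -0.52 and the list still passed. Without Adtet array 1, 2 or 3 limma called 0 members in each case, with 19, 18 and 23 at an unadjusted p under 0.05, while the list's medians were -0.90, -0.90 and -0.87 and the list stayed past the threshold. Without IκB array 2 it was 4.

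Immediate early genes, which growth factors and cytokines induce within minutes, had 5 of 25 members lower and none higher. Their median log2 fold change was -0.25 (camera adjusted p = 0.0012), against -0.42 without IκB array 1 and -0.17 without IκB array 3. The list call was lost with an estimated correlation (adjusted p = 0.117). IER3, CCN1, CCN2, JUNB and NR4A3, of which 2 of 4 probe sets passed, were the 5, and CCN1 fell 1.91-fold from 721 ± 51.0 (SD, n = 3) to 376 ± 24.6. Over the list alone 7 were lower. By fry, all 7 lists that passed camera were lower, with adjusted p from 3.08e-05 to 0.0126. Without IκB array 2, Adtet array 1 or Adtet array 2 the count of lower members was 2, and the NR4A3 call was lost (adjusted p 0.057 to 0.0664). The JUNB call was lost without any 1 array other than IκB array 1 (adjusted p 0.0551 to 0.136).

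**Figure D2:**
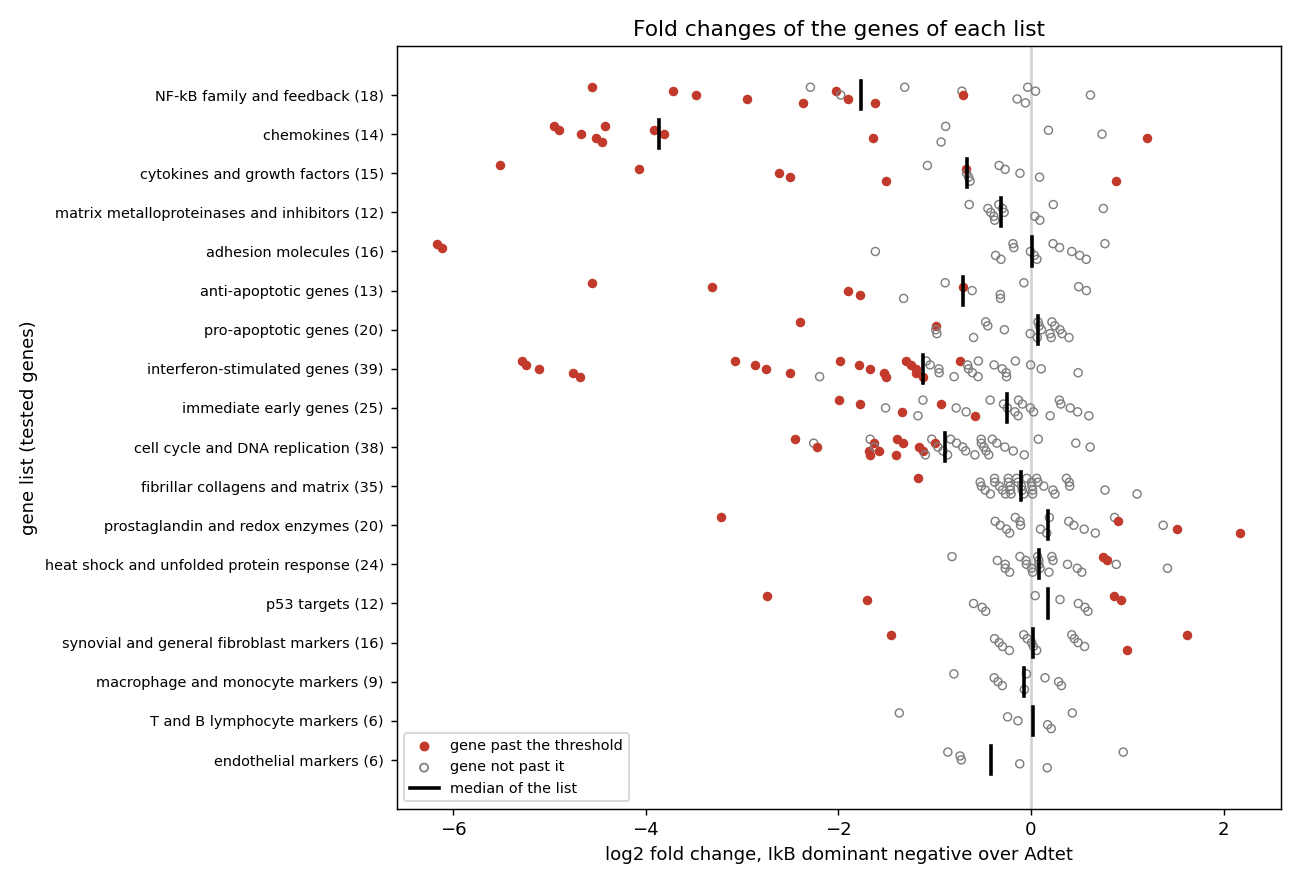
Log2 fold change of each tested gene (x axis, IκB dominant negative over Adtet) in each of the 18 gene lists (y axis, number of tested genes in parentheses), where filled points passed the threshold, open points did not, and vertical bars are list medians. The chemokine median lies at -3.86, and those of interferon-stimulated and cell cycle genes at -1.12 and -0.89.

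None of 12 matrix metalloproteinase and inhibitor genes passed, also over the list alone, and 2 had an unadjusted p under 0.05 in limma (camera adjusted p of the list 0.342). Their median log2 fold change was -0.31, but -0.17, -0.15 and -0.20 without IκB array 1, IκB array 2 or Adtet array 3, and -0.039 without the filter. MMP14, a membrane-bound collagenase, read 417 ± 24.0 (SD, n = 3) with the IκB dominant negative and 252 ± 56.4 with Adtet (adjusted p = 0.0742). The probe set of MMP13 lay at or below the floor on all arrays and that of MMP3 on all but 1. A second TIMP2 probe set was lower (log2 fold change at most -2.42), whereas the one that represented the gene was at -0.39 and did not pass. Of 35 fibrillar collagen and matrix genes only THBS1, which encodes thrombospondin 1, passed, by both adjustments (2.26-fold lower, camera adjusted p of the list 0.171). The 3 probe sets of THBS1 ranged from -1.18 to 0.19. Without IκB array 3 the collagen list was lower, at an adjusted p of 0.0171 within a range of 0.0171 to 0.566 over its alternatives, while THBS2 was higher (adjusted p = 0.0425).

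Prostaglandin and redox enzymes moved both ways and did not pass as a list (camera adjusted p = 0.298). Of 20 members 3 rose and 1 fell, and 5 were higher and 2 lower over the list alone. HMOX1 rose 4.51-fold, from 215 ± 70.4 (SD, n = 3) to 942 ± 112. Catalase (CAT) rose 2.85-fold and PTGS2, the inducible cyclooxygenase, 1.88-fold. GCH1, which opens tetrahydrobiopterin synthesis, was at least 9.30-fold lower. The PTGS2 call was lost without IκB array 2 or any 1 of the Adtet arrays (adjusted p 0.0507 to 0.0761), and that of CAT without IκB array 2 (adjusted p = 0.05), which left 1 higher member.

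The heat shock and unfolded protein list did not pass (camera adjusted p = 0.151). DNAJB1 rose 1.68-fold and HSPA4 1.72-fold, 2 of 24 members, with 3 higher over the list alone. By fry the list was higher (adjusted p = 0.0185). The HSPA4 call was lost without any 1 array (adjusted p 0.0677 to 0.153), and that of DNAJB1 without IκB array 2 or any 1 of the Adtet arrays (adjusted p 0.084 to 0.0968), where limma called 0 members, with 5, 5, 8 and 4 at an unadjusted p under 0.05. Without IκB array 1 the heat shock list passed camera at an adjusted p of 0.0165, within a range of 0.0165 to 0.480 over its alternatives, and it also passed under quantile normalization and without the filter.

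Of 12 p53 target genes 2 fell and 2 rose, and the list did not pass (camera adjusted p = 0.895). Its median (0.17) and mean (-0.19) differed in sign, and the median ranged from -0.064 without IκB array 1 to 0.28 without IκB array 3. PLK2 fell 6.69-fold from 532 ± 47.8 (n = 3) to 81.3 ± 22.7, and GADD45A 3.26-fold. DDB2 rose 1.82-fold and CCNG1 1.91-fold. Over the list alone 3 were higher and 2 lower. The DDB2 and CCNG1 calls were both lost without IκB array 2 or any 1 of the Adtet arrays, where limma called 0 higher members, with 5, 6, 4 and 6 of the list at an unadjusted p under 0.05. CCNG1 also lost its call without IκB array 3. The highest adjusted p were 0.081 for DDB2 and 0.0983 for CCNG1.

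Among genes past the threshold, each represented by 1 probe set with 1 symbol, the largest rises after DUSP4 were those of ETFB, MTCL1, SULT4A1, THBD and NOTCH3. DUSP4 read 551 ± 77.1 (SD, n = 3) against 12.3 ± 4.20, the latter below the floor (adjusted p = 6.4e-05). ETFB, which encodes a subunit of the electron transfer flavoprotein, rose at least 6.46-fold, with 1 of the 3 Adtet arrays at or below the floor, and MTCL1 5.91-fold. THBD, which encodes thrombomodulin, rose 5.56-fold from 68.2 ± 11.5 to 376 ± 10.5, and the receptor gene NOTCH3 5.55-fold. SULT4A1 rose 5.73-fold by 1 probe set, and its other probe set was at -0.00 on the log2 scale. MAT2A, which makes S-adenosylmethionine, TIPARP, NFIL3, the aldo-keto reductase gene AKR1B10 and the lipid droplet gene PLIN2 rose between 4.36-fold and 5.05-fold, which for AKR1B10 is a lower bound, with 1 Adtet array at or below the floor. The calls of AKR1B10 and NFIL3 were lost without IκB array 1 (adjusted p 0.053 and 0.0559) or IκB array 2 (0.0815 and 0.0575), and that of AKR1B10 also without Adtet array 1 or 2 (0.0881 and 0.0839).

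Fibroblast markers did not pass as a list (camera adjusted p = 0.680, 16 genes). HAS2, a hyaluronan synthase, rose 3.08-fold from 176 ± 28.8 (SD, n = 3) to 540 ± 80.9, and PDGFRB from 512 ± 76.8 to 1022 ± 157, while PDPN, which encodes podoplanin, fell 2.73-fold. Over the list alone 3 were higher and 1 lower. Of PDGFRB and PDPN 1 of 2 probe sets passed each. The PDGFRB call was lost without any 1 array other than IκB array 1 (adjusted p 0.054 to 0.0831) and the PDPN call without any 1 other than IκB array 2 (adjusted p 0.0531 to 0.113).

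None of 9 macrophage, 6 lymphocyte or 6 endothelial markers passed, also over each list alone. In limma 0, 0 and 1 of them had an unadjusted p under 0.05, and the lists had camera adjusted p of 0.607, 0.839 and 0.362. The median (0.02) and mean (-0.16) of the lymphocyte list differed in sign, and its median lay below 0 under both other scalings (-0.080 and -0.12) and ranged from -0.10 without IκB array 2 to 0.17 without Adtet array 1. Without IκB array 1 the macrophage gene CSF1R was lower (log2 fold change -1.60, adjusted p = 0.0431). CD68 read 485 ± 191 with the IκB dominant negative and 581 ± 141 with Adtet (n = 3), and the CD14 probe set lay at or below the floor on all 6 arrays.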

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

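The settings that raised the floor to the 60th percentile, set it at the 20th percentile of positive values or took a generalised log2, and the unblocked fit on 4 arrays, were chosen after seeing the data. A floor at the 20th or 5th percentile of all values and log2 of the value plus the 20th percentile were planned and not run, because -6.5 and -87.6 cannot serve there. The total of 392 probe sets ranged from 303 to 423 under the 2 other scalings, both filters, both variance models, the gene level and the 3 added floor settings, and was 294 with a 2-fold minimum, which left 113 higher. Array weights gave 1442 (830 higher, 612 lower), so the higher share went from 45.2% to 57.6%. An adjusted p under 0.10 gave 737 (400 and 337). With single arrays left out, totals ranged from 163 to 352, with 57 to 174 higher and 94 to 195 lower, in fits with fewer arrays. The titles of both groups share only the numbers 2 and 3, since that of IκB array 1 carries none, and deviations from group means correlated at -0.083 and -0.0012 between arrays of 1 number, so the numbers were not taken as pairs. With the replicate block on those 4 arrays, limma called 0 probe sets (0 higher, 0 lower; 999 at an unadjusted p under 0.05), and without the block it called 97 (29 and 68). NFKBIA was at -3.25 in both, with adjusted p of 0.165 and 0.0717, against 5.8e-05 to 0.0303 in its other fits. The block left 1 residual degree of freedom. Immediate early genes (median -0.25) lost their call with an estimated correlation (adjusted p = 0.117; 0.000642 to 0.0171 in the other settings). The heat shock list gained one under quantile normalization (median 0.20), without a filter (0.082) and on the 4 arrays with and without the replicate block (0.16 in both), and medians ran from 0.057 to 0.18 with single arrays left out, the highest, without IκB array 1, past the threshold. With single arrays left out, medians ran from -0.13 to 0.033 for adhesion molecules and from -0.20 to -0.026 for collagens, the lowest of each past the threshold. Over all settings they ran from -0.22 to 0.056 and from -0.20 to -0.012, and the adhesion value of -0.22, on the 4 arrays, did not pass (adjusted p = 0.0788 with the block and 0.0782 without). The immediate early median was -0.16 with array weights, -0.42 with the generalised log2 and -0.46 on the 4 arrays. The causes of these shifts were not tested. The other 6 lists that passed did so in every setting run. No named gene called in either fit changed sign, and no list called in either changed its camera direction. The adhesion median did change sign, from 0.014 in the main fit to -0.13 without IκB array 1, where that list passed. Of 58 named genes past the threshold 37 stayed past it in each setting on 5 or 6 arrays, and 20 lost it with some single array left out, with adjusted p up to 0.153. Without the filter IFITM1, AKR1B10, NFIL3, IL1RN, TRAF1, BID, JUNB, CDC20, TPX2, HSPA4, PDGFRB and PDPN lost it (adjusted p 0.0566 to 0.12). The generalised log2 ended the calls of IFITM1, AKR1B10, IL32, BID and HSPA4, the floor at the 60th percentile those of AKR1B10, NR4A3, BUB1B and HSPA4, eBayes without trend those of JUNB, DNAJB1, HSPA4 and PDGFRB, the gene level those of TRAF1 and PDPN, and quantile normalization and robust eBayes that of HSPA4. With 22.4% to 26.5% of values at or below 0, folds of dim genes are bounded by the floor.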

Other observations

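The complement, oxidative phosphorylation, proteasome and ribosomal lists, the tests of IκB array 1, both tests of the higher genes and the test of detoxification genes were chosen only after the result was seen. Complement genes CFB, C1S and C1R were lower with the IκB dominant negative, 3 of 11 tested. C1S, the protease that starts the classical cascade with C1R, fell from 1291 ± 166 (SD, n = 3) to 584 ± 66.1, and C1R from 575 ± 114 to 295 ± 60.7. CFB, the protease of the alternative pathway, had a log2 fold change of at most -4.12 (limma adjusted p = 0.00166). The list had a camera adjusted p of 0.0277 over 5 lists, and the call was lost with an estimated correlation (adjusted p = 0.128) and without IκB array 1 (adjusted p = 0.0863).

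Of 53 oxidative phosphorylation genes 47 had log2 fold changes above 0, with a median of 0.35 and 2 past the threshold, ATP5MC3 and COX7C. Camera called the list at an adjusted p of 7.63e-06, a call lost with an estimated correlation (adjusted p = 0.0721). Proteasome subunits other than PSMB8, PSMB9 and PSMB10 had 26 of 30 above 0 and a median of 0.32. None passed the limma threshold and 14 had an unadjusted p under 0.05 (camera adjusted p of the list 2.68e-05, and 0.128 with an estimated correlation, which ends the call). The immunoproteasome genes PSMB8 and PSMB9 were lower. Ribosomal protein genes had a median of -0.23 over 44 genes, of which 0 had an unadjusted p under 0.05 in limma (camera adjusted p = 0.000954, and 0.561 with an estimated correlation, which ends the call). That median was -0.058 without IκB array 1, and the list no longer passed (adjusted p = 0.611). ID1 and ID3, related inhibitors of basic helix-loop-helix factors, had log2 fold changes of opposite sign. Those of ID1 were 1.75 and 1.90 at both of its brighter probe sets, and that of ID3 was -0.73. Both genes were chosen after their values were seen, and whether they passed the threshold is not stated here.

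The probe sets of type I and type II interferon genes were dim while 20 interferon-stimulated genes fell. Of 16 such probe sets 11 lay at or below the floor on all 6 arrays, that of IFNB1 among them, and none entered the test. With Adtet the IFNB1 probe set had a median of -12 over 3 arrays.

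IκB array 1 stood apart from the other arrays by its control probe sets and correlations. A label belonging to the Adtet group would put its chemokines near the Adtet mean, but their median on this array was -3.50 from it, near the -4.11 and -3.89 of IκB arrays 2 and 3, which argues against it. A weaker response to bright targets stays open. The spread of log2 values over bright probe sets, relative to the other arrays of its group, was 1.02 and inside the range of the other 5 arrays (0.990 to 1.09), but its median difference from the other arrays of its group over the 10% brightest of these was -0.36 on the log2 scale, the lowest of the 6 arrays. On each of the BioB, BioC, BioDn and CreX control probe sets IκB array 1 was the lowest of the 6 arrays. Those of CreX read 1454 and 1611 on it, against 2094 to 3128 and 2112 to 2819 on the others. BioB-5 and BioC-3 were lower on every IκB array than on any Adtet array, and for the rest of these controls the groups overlapped. The RNA time, which the label of IκB array 1 leaves out, was not tested.

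The 139 genes that were higher could reflect a scaling that lifts all genes when bright ones fall, or noise near the floor. The first would raise all probe sets alike, whereas the median log2 fold change of all tested probe sets was 0.020. The smallest among those called higher was 0.52, which does not bear on this, because the threshold itself keeps small changes out. For the second, 7.91% of the probe sets called higher had all 3 Adtet arrays at or below the floor. That share leaves out probe sets with only some Adtet arrays there, such as those of AKR1B10 and ETFB, so it cannot decide on noise near the floor. The median of all probe sets argues against a uniform lift as the cause of the whole pattern. Quantile normalization, which gives every array the same distribution of values, called 200 probe sets higher, against 177 with the values as deposited. The higher calls thus did not shrink when differences between arrays that depend on intensity were evened out. Forcing 1 distribution can itself lift genes when bright ones truly fall, so a scaling effect that depends on intensity stays open. An effect of holding NF-κB is a hypothesis that remains, and differences between the viruses other than the transgene were not tested.

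The fall of cell cycle genes could come from a bias of dim probe sets or from IκB array 1. Against the first, the list's median of -0.89 lay at percentile 0.01 of the medians of 10000 random lists matched on mean expression, the smallest these draws can give, and the lowest random median was -0.45. Against the second, the median without that array was -0.92. Proliferation, cell density and viral load were not measured, and no biological explanation was tested.

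HMOX1, AKR1B10 and AKR1C3 were higher, and a joint rise of NRF2-type and aldo-keto detoxification genes was set up as a hypothesis. Of 19 tested members 17 had log2 fold changes above 0 and 5 passed the threshold, among them MGST3 and TKT. Camera called the full list (adjusted p = 2.68e-05), a call lost with an estimated correlation (adjusted p = 0.0721). Without HMOX1, AKR1B10, AKR1C3 and TKT, the 15 remaining genes had a median of 0.47 and a camera adjusted p of 0.00749. Of these 15 the adjusted p with an estimated correlation was 0.166, so the hypothesis stays open. NQO1, a usual NRF2 target, was at 0.10 and FTL at -0.91, neither past the threshold.

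Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 392 probe sets, and the highest of the others gave 0 (140 to 469 at an unadjusted p under 0.05 in limma, against 1656). For gene lists past the camera threshold it was again 1 split of 10, with 7 lists in the real split and 5 in the highest of the others. The splits are too few for a share under 0.05. Each of the others also puts arrays of both groups on both sides. The real difference then enters the spread within a side, which works against probe set calls, and part of it stays between the sides. Their counts are therefore not a rate of calls without a group difference.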
